A study of Homo sapiens with 6 samples.

How the data were processed

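RNA was sequenced from 6 samples of HCT116 cells, an established human colorectal cancer line. Of these, 3 had been treated with a control siRNA called si NC and 3 with an siRNA against PLOD3, each for 2 days, per the labels' protocols. The cells were grown in DMEM with 10% fetal bovine serum at 37 °C and 5% CO2, and total RNA was isolated with RNAiso Plus, starting cDNA synthesis from 1 µg. Ribosomal RNA was depleted with a Ribo-Zero kit before the libraries were made, per the labels' protocols, which in principle leaves RNA without a poly(A) tail in. Levels of such RNA were low in si NC, at a mean FPKM of 1.14 for RN7SK and 0.311 for RMRP (n = 3). How far it was recovered is thus uncertain. Each sample's group came from its title, and the replicate numbers came from the same titles. Nothing in the labels says that the 3 samples of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical.

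The authors deposited 1 table with 60612 genes and 12 columns of values, an FPKM and a count for each sample, and 0 value columns were left unmapped. FPKM (fragments per kilobase of transcript, scaled to the mapped fragments) were deposited unscaled between samples, per the file headers, with 0.0001 written for a gene without reads. The second set of columns holds estimated counts, deposited as whole numbers and not normalized, per the file headers. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4 and StringTie 1.3.4d. The genome build, the annotation release, the strand setting and the way the counts were made are not given in the sources used here. In the table, the ratio of a gene's count to its FPKM was constant between samples after a factor per sample, with a median coefficient of variation of 0.0288% over 7070 genes. Low counts piled up at multiples of 4: a sample had on average 1490 genes at a count of 4, 558 at 3 and 312 at 5. A read pair was therefore worth about 4 units, the counts overstate the number of read pairs, and counting noise is larger than the counts alone would give. The edgeR test takes the spread from the replicates and covers this, and dividing the counts by 4 was tried as an alternative. Of the genes in the table, 58394 (96.3%) were found by identifier in the GENCODE annotation of the GRCh38 assembly given with the data, and 99.98% of those overlapped their annotated position, so the table's coordinates were read as GRCh38. Without a stated strand setting, reads of a gene and of a partner on the opposite strand cannot be told apart.

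The design fixed before the data were examined named limma on log2(FPKM + 1), with edgeR to replace it if the values turned out to be counts. As the table holds estimated counts beside the FPKM, edgeR 4.0.16 in R 4.3.3 was used for the main results and limma 3.58.1 for alternatives. The counts, already whole, were used as deposited. Genes with a mean FPKM of at least 1 over all 6 samples were kept, which left 12000. Counts were scaled by TMM, dispersions were estimated with a trend, and the 2 groups were compared with edgeR's quasi-likelihood test (two-sided, Benjamini-Hochberg adjusted, threshold 0.05), with all 6 samples and no covariate. Fold changes are log2 values of PLOD3 siRNA relative to si NC, and levels are the mean deposited FPKM ± SD with n = 3 per group. A count of genes past 1.5-fold takes the called genes with at least that fold change. For single genes an exact permutation test of 3 against 3 values cannot go below 0.1.

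In all, 30 gene lists were fixed before the data were examined, including 3 lists of markers of fibroblasts, leukocytes and endothelial cells, and PLOD3 itself is in none of them. The 26 lists with at least 5 tested members were compared with the other genes by camera with a preset correlation of 0.01, adjusted over the 26 lists. Beside it stand camera with the correlation estimated per list and fry, which tests whether a list's members move, on balance, one way. The table pairs genes with Gene Ontology and KEGG terms, and 3142 terms of 10 to 500 genes were tested for each direction with a one-sided Fisher's exact test against 10407 tested genes with at least 1 term. Genes named in the text were chosen by a rule fixed before the data were examined: PLOD3, PLOD1 and PLOD2, then the 12 highest and 12 lowest fold changes among called genes with a mean FPKM of at least 2 in the higher group, a symbol that is not a clone name and no overlap between the groups, then up to 4 members per list with the smallest p. Because the 12 highest were all short noncoding RNAs, the 12 highest protein-coding genes by the same rule were added after their values were seen. Members that make up a count of 5 or fewer in a list were likewise named after their values were seen.

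GC content and length were taken from the longest coding transcript of each gene, or its longest transcript, in GENCODE, and 11968 of the tested genes had a value. For the GC correction, a loess trend (span 0.5) of each library's log2 CPM (counts scaled to the library total) against GC content was removed as an offset before the edgeR test. This correction, the correction for GC and length, DESeq2 1.42.0, limma on log2(FPKM + 1) as an alternative to edgeR, relative log expression scaling, counts divided by 4, and fits without noncoding genes or without genes that step between replicates were chosen after seeing the data. Leaving out each sample in turn, other filters, a replicate block, and for limma a pseudocount of 0.1, median centring, quantile normalization, TPM, no trend and sample weights were fixed before.

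The fits were tested on simulated data: counts for the 12000 genes with 100 genes changed 1.5-fold and 100 changed 2-fold. In the simulation of this comparison edgeR recovered 13 of the 1.5-fold and 62 of the 2-fold changes and called 3 unchanged genes. Far fewer genes changed there than the 35.5% called in the real data. The adjusted threshold was thus stricter in the simulation, and these recoveries do not carry over to the real samples. With each library's own linear GC trend added, 99 unchanged genes were called, and 5 after the GC correction. A list of changed genes planted in the simulation was called by camera (adjusted p = 5.7e-27) and with an estimated correlation (adjusted p = 0.0115), while 0 of 50 random lists were called by either. The simulated genes varied independently, so this check cannot show false calls in lists whose members vary together. In splits of the real samples that mixed the groups, camera with the preset correlation called up to 12 of the 26 lists. Replicates of one group were also compared with each other: the chi-square per degree of freedom, on counts divided by 4, was 22.9 to 33.6 within groups and 43.6 to 95.2 between groups, so no 2 libraries differed as little as sampling noise. The figures were drawn with matplotlib 3.10.9. Sequence variants, exon usage and isoforms were not analysed here.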

Results

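HCT116 is an epithelial cell line from a human colorectal cancer, and the series asks what PLOD3 does in the progression of that disease. RNA-seq after removal of ribosomal RNA gave values for 3 samples treated with the control siRNA si NC and 3 treated with PLOD3 siRNA. The estimated counts summed to 57457602, 65369061 and 76802428 for si NC replicates 1 to 3 and to 71736017, 55416555 and 55537121 for PLOD3 siRNA replicates 1 to 3, where about 4 units stand for 1 read pair. On log2 CPM (counts scaled to the library total), Pearson's r across genes was 0.961 to 0.971 between samples of one group and 0.935 to 0.951 between groups, and the first principal component, with 43.6% of the variance, separated the groups.

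PLOD3 was lower in all 3 PLOD3 siRNA samples than in any si NC sample, which bears on whether the siRNA acted on its target. PLOD3 (ENSG00000106397, chromosome 7, 101205977 to 101218366, minus strand, GRCh38) encodes a lysyl hydroxylase and glycosyltransferase that modifies collagen. Its FPKM was 6.40, 7.16 and 6.22 in si NC and 3.44, 3.40 and 4.05 in PLOD3 siRNA. The mean fell from 6.59 ± 0.501 to 3.63 ± 0.364 (SD, n = 3 each), or to 55.1% of the control, with a log2 fold change of -0.85 (SE 0.107, edgeR adjusted p = 0.0035). The two-sided exact permutation test of the 3 against 3 values gave p = 0.1, the smallest it can give. After the GC correction PLOD3 stood at 69.96% of the control (log2 -0.52, adjusted p = 0.0074). The end of PLOD3 overlaps ZNHIT1 on the other strand, whose FPKM was 8.004 ± 0.651 in si NC and 8.41 ± 1.16 in PLOD3 siRNA (n = 3 each, edgeR adjusted p = 0.695).

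Of the other lysyl hydroxylase genes, PLOD1 fell from 38.6 ± 1.48 to 28.5 ± 2.58 FPKM (n = 3 each, log2 -0.44, edgeR adjusted p = 0.00933). That call was lost after the GC correction (log2 -0.16, adjusted p = 0.085). PLOD2 stood at 3.77 ± 0.504 and 3.58 ± 0.130 FPKM (n = 3 each), a log2 difference of -0.07 that did not pass the test (edgeR adjusted p = 0.678), and it passed after the GC correction at -0.37 (adjusted p = 0.043) but not after the GC and length correction (adjusted p = 0.0811).

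**Figure D1:**
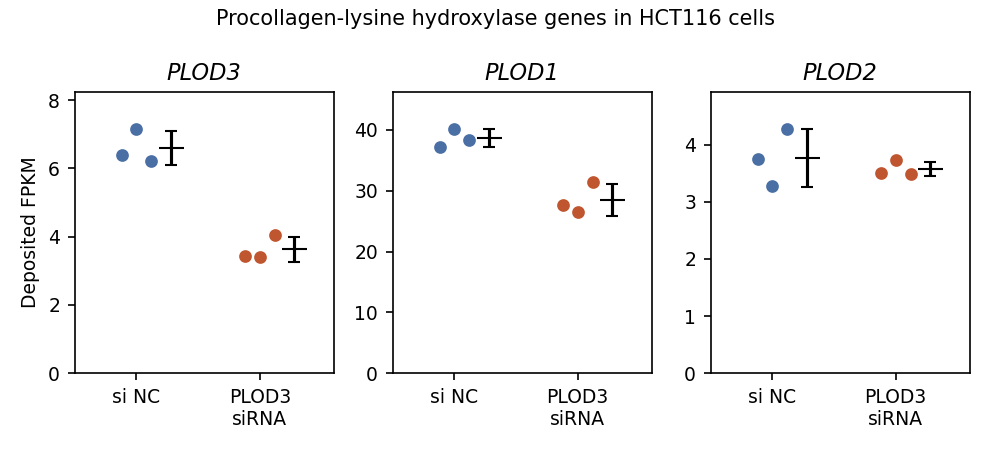
Deposited FPKM of PLOD3, PLOD1 and PLOD2 in the 6 samples. Points are samples, and the bar beside them is the mean ± SD of 3 samples. PLOD3 lies at 6.22 to 7.16 in si NC and at 3.40 to 4.05 in PLOD3 siRNA, while the PLOD2 values of the groups overlap.

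Beyond PLOD3, camera called lists of matrix, adhesion, Wnt, TGF-beta and MAPK genes as lower in PLOD3 siRNA and lists of cell cycle genes as higher, although in each list some members did not pass. These calls were lost with an estimated correlation (adjusted p = 0.128 to 0.248 with an estimated correlation). With the preset correlation, camera also called up to 12 lists in splits of the samples that mixed the groups but kept part of their difference. TIMP2, an inhibitor of matrix metalloproteinases, fell from 22.6 ± 1.04 to 5.14 ± 1.81 FPKM (n = 3 each, log2 -2.14), and COL6A1, a chain of collagen VI, from 22.5 ± 0.127 to 8.73 ± 1.28 (n = 3 each, log2 -1.37). HMMR, a spindle-associated protein and hyaluronan receptor, rose from 9.79 ± 0.832 to 21.0 ± 1.67 FPKM (n = 3 each, log2 1.11), and HMOX1, the enzyme that breaks down heme, from 11.1 ± 0.544 to 31.6 ± 0.570 (n = 3 each, log2 1.51). Over all 12000 genes tested with edgeR, 1945 were higher and 2319 lower, of which 667 and 1100 changed at least 1.5-fold, and 91 and 241 at least 2-fold. The groups did not overlap in 6251 genes (52.1%), against 10% from chance.

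Without si NC replicate 3 the counts were 1106 higher and 1509 lower, and without PLOD3 siRNA replicate 1 they were 1083 and 1530. With values rescaled to TPM, limma called 2470 higher and 1461 lower, a share of 62.8% higher against 45.6%, and after the GC correction 1062 genes rather than 1767 passed 1.5-fold.

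The lowest genes by the fixed rule were BIVM-ERCC5, APOLD1, LEMD1, OLFM2, TIMP2, SUSD2, SYNPO, CCDC92, METTL7A, TGM2, GFY and NOTUM. Among them, TGM2, a transglutaminase that crosslinks proteins, fell from 3.22 ± 0.0592 to 0.827 ± 0.0689 FPKM (n = 3 each, log2 -1.95), and OLFM2 from 17.6 ± 1.20 to 3.84 ± 1.92 (n = 3 each, log2 -2.19). NOTUM, a secreted enzyme that inactivates Wnt proteins, fell from 4.77 ± 0.295 to 1.28 ± 0.245 (n = 3 each, log2 -1.89). The readthrough gene BIVM-ERCC5 overlaps ERCC5 on the same strand, and the 2 moved in opposite directions: BIVM-ERCC5 from 4.14 ± 0.962 to 0.109 ± 0.189 FPKM and ERCC5 from 0.929 ± 0.381 to 4.29 ± 0.194 (n = 3 each). Their values are uncertain because reads of one can be assigned to the other, and BIVM-ERCC5 kept its edgeR call only without PLOD3 siRNA replicate 3, with an adjusted p of 0.0571 to 0.0736 without each of the others, and lost it in DESeq2 (0.0997).

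The 12 highest genes were all short noncoding RNAs. The signal recognition particle RNAs RN7SL1 and RN7SL2 rose from 3.32 ± 1.19 to 78.7 ± 12.4 FPKM and from 2.01 ± 0.538 to 96.7 ± 10.9 (n = 3 each, log2 4.57 and 5.57), and RN7SL3 and RN7SL4P by 4.76 and 5.17 on the log2 scale. RN7SK, which holds back transcription elongation, rose by 3.69, the RNase P RNA RPPH1 by 4.25, and the 5.8S ribosomal RNA copies RNA5-8SN1, RNA5-8SN2 and RNA5-8SN3 by 3.49, 3.51 and 3.54. Another 5.8S copy on chromosome 21 (ENSG00000277739) rose by 3.52. The RNase MRP RNA RMRP (ENSG00000277027) rose from 0.311 ± 0.121 to 4.80 ± 1.39 FPKM (n = 3 each, log2 3.86, edgeR adjusted p = 0.00242). The RN7SL copies and the 5.8S copies are near-identical, and how reads were split among them is uncertain. RNA5SP202 was listed without reads in all si NC samples and at 0.537, 2.79 and 3.67 FPKM in PLOD3 siRNA replicates 1 to 3, and its edgeR call was lost without si NC replicate 2 or 3 (adjusted p = 0.0549 and 0.0544) and without PLOD3 siRNA replicate 2 or 3 (0.0840 and 0.0676), as it was in limma with sample weights (0.0515).

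The highest protein-coding genes, chosen after their values were seen, were NIPA1 (log2 2.27), ERCC5 (2.20), HMOX1 (1.51), PRXL2B (1.45), HACD3 (1.44), DDX60 (1.35), LAMTOR3 (1.34), SYBU (1.27), ZMAT3 (1.20), FAM72B (1.20), RADX (1.19) and C6orf226 (1.18). The magnesium transporter NIPA1 rose from 1.10 ± 0.539 to 5.25 ± 1.06 FPKM and ZMAT3, a p53 target that binds RNA, from 0.989 ± 0.324 to 2.27 ± 0.168 (n = 3 each). HACD3 kept its edgeR call only without PLOD3 siRNA replicate 1, with an adjusted p of 0.0679 to 0.0970 without each of the others, and lost it after the GC correction (adjusted p = 0.0635) and in limma on log2(FPKM + 1) (0.0535). FAM72B has near-identical copies, so its level is uncertain.

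Many matrix genes fell. In the list of collagens and basement membrane proteins, 13 of 17 tested members fell and 0 rose (14 lower adjusted over the list alone), with a median log2 fold change of -0.78 (camera adjusted p = 3.7e-11). That call was lost with an estimated correlation (adjusted p = 0.143 with an estimated correlation). Besides COL6A1, HSPG2, the basement membrane proteoglycan perlecan, fell, COL18A1 fell by 0.98 on the log2 scale and the laminin chain LAMB2 by 0.93. Of the matrix proteases and their inhibitors, 8 of 17 fell and 2 rose (10 and 3 adjusted over the list alone), with a median of -0.47 (camera adjusted p = 0.00426, adjusted p = 0.217 with an estimated correlation). The inhibitors TIMP2 and TIMP3 (log2 -1.10) fell, as did the proteases PLAU (-0.59) and CTSB (-0.49), while ADAM9 and CTSL rose by 0.31 each. ADAM9 lost its call after the GC correction (edgeR adjusted p = 0.557). In the 6 fits that left out a sample, ADAM9 kept the call in 2 and CTSL in 1. The GC-corrected medians of these 2 lists were -0.50 and -0.26 (camera adjusted p = 3.7e-07 and 0.0113).

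The list closest to the function of PLOD3, enzymes and chaperones that modify collagen lysine and proline, did not pass camera (median -0.23, camera adjusted p = 0.0565). It was called as lower by fry (fry adjusted p = 0.00708). Its GC-corrected median was -0.10 (camera adjusted p = 0.456). In it 7 of 18 members fell and 2 rose (8 and 3 adjusted over the list alone). LOXL2, a lysyl oxidase that starts collagen crosslinks, fell from 7.17 ± 0.371 to 2.66 ± 0.321 FPKM (n = 3 each, log2 -1.42). LOXL1 (-0.86) and BMP1 (-0.47) fell and P4HA1 (0.64) and PPIB (0.27) rose. The edgeR calls of LOXL1, BMP1 and P4HA1 were lost after the GC correction (adjusted p = 0.0797, 0.275 and 0.0819).

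Many adhesion genes fell as well. Of 24 integrin and focal adhesion genes, 16 fell and 0 rose (16 adjusted over the list alone), with a median of -0.42 (camera adjusted p = 2.4e-06, adjusted p = 0.234 with an estimated correlation). The laminin receptor subunits ITGB4 and ITGA3 fell, the former from 27.5 ± 1.86 to 12.6 ± 2.20 FPKM (n = 3 each), TNS3 fell by 1.26, and vinculin (VCL), which ties adhesions to actin, by 0.63. Of 30 epithelial junction and keratin genes, 11 fell and 0 rose (11 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 0.00142, adjusted p = 0.248 with an estimated correlation). Plakoglobin (JUP), a desmosome protein, fell from 53.9 ± 0.310 to 26.3 ± 6.88 FPKM (n = 3 each, log2 -1.04), the tight junction genes CLDN3 and TJP3 by 1.22 and 0.93, and SPINT1 by 0.96. Of 10 mesenchymal genes, 6 fell and 0 rose (7 lower and 1 higher adjusted over the list alone), with a median of -0.53 (camera adjusted p = 0.00564, adjusted p = 0.276 with an estimated correlation). Fibronectin (FN1) fell by 1.46, S100A4 by 0.93 and ITGA5 by 0.57, and ITGA5 lost its call after the GC and length correction (log2 -0.21, edgeR adjusted p = 0.0698). The GC-corrected medians of the 3 lists were -0.31, -0.19 and -0.30, with camera adjusted p = 0.000125, 0.0147 and 0.0651, so that the mesenchymal list lost its call, as it did under quantile normalization (0.0535).

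Many targets of growth and developmental signals fell. Of 18 Wnt and beta-catenin targets, 11 fell and 1 rose (the same counts adjusted over the list alone), with a median of -0.53 (camera adjusted p = 0.000565, adjusted p = 0.2 with an estimated correlation). SOX9, a transcription factor of intestinal progenitors, fell from 17.9 ± 0.928 to 9.08 ± 1.66 FPKM (n = 3 each, log2 -0.98), the Wnt receptor ligase RNF43 by 0.76 and EPHB3 by 0.79. EPHB3 lost its call after the GC and length correction (log2 -0.36, edgeR adjusted p = 0.0599). The member that rose, MYC, a growth-promoting transcription factor, was at 4.01, 5.01 and 4.17 FPKM in si NC and at 37.5, 3.14 and 38.9 in PLOD3 siRNA replicates 1 to 3. Its edgeR adjusted p was 0.0487, and without PLOD3 siRNA replicate 2 it was 0.00333, while the call was lost without any other sample (0.113 to 0.121) and after the GC correction (0.0556). Of 20 TGF-beta targets, 13 fell and 0 rose (14 and 1 adjusted over the list alone), with a median of -0.37 (camera adjusted p = 0.000486, adjusted p = 0.128 with an estimated correlation). TGFB1, the growth factor itself, fell from 18.1 ± 0.877 to 8.24 ± 0.227 FPKM (n = 3 each, log2 -1.13), and SKI and TGIF1 by 0.59 and 0.47. Of 28 MAPK and immediate early genes, 14 fell and 1, MYC, rose (17 and 2 adjusted over the list alone), with a median of -0.33 (camera adjusted p = 0.000565, adjusted p = 0.248 with an estimated correlation). The phosphatase DUSP4 fell by 0.66 and the ETS factor ETV5 by 0.58. Of 20 NF-kappaB targets, 6 fell and SOD2 (0.35) rose (7 and 1 adjusted over the list alone), with a median of -0.27 (camera adjusted p = 0.00877, adjusted p = 0.143 with an estimated correlation). SOD2 lost its call after the GC correction (edgeR adjusted p = 0.372) and kept it in 2 of the 6 fits that left out a sample. TNFAIP2 fell by 0.77, BCL3 by 0.82 and ICAM1 by 0.65. The GC-corrected medians of these 4 lists were -0.47, -0.20, -0.28 and -0.17, and only the NF-kappaB list lost its camera call (adjusted p = 0.22). The Wnt list lost its call when only genes with a mean FPKM of at least 5 were kept (0.158).

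Many cell cycle genes rose. Of 40 genes of the G2 and M phases, 30 rose and 0 fell (32 adjusted over the list alone), with a median of 0.56 (camera adjusted p = 1.3e-14, adjusted p = 0.128 with an estimated correlation). Cyclin A2 (CCNA2) rose from 27.0 ± 0.773 to 48.1 ± 0.850 FPKM (n = 3 each, log2 0.84), and the mitotic checkpoint kinases TTK and BUB1 by 0.95 and 0.73. Of 40 genes of the G1 and S phases, 21 rose and 1 fell (21 and 2 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 0.000245, adjusted p = 0.128 with an estimated correlation). RRM1, the large subunit of ribonucleotide reductase, rose by 0.69, the replication factors MCM10 and RFC5 by 0.76 and 0.59, and E2F1 fell by 0.60. The GC-corrected medians were 0.39 and 0.25 (camera adjusted p = 1.5e-12 and 2.9e-06).

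Of 33 p53 targets, 15 rose and 4 fell (the same counts adjusted over the list alone), with a median of 0.28 (camera adjusted p = 0.00404, adjusted p = 0.128 with an estimated correlation). TRIAP1, an inhibitor of apoptosis, rose from 22.8 ± 1.04 to 42.1 ± 2.23 FPKM (n = 3 each, log2 0.89), and POLH, BLOC1S2 and GADD45A also rose. CCNG1 (-0.89), GDF15 (-0.33), XPC (-0.29) and the death receptor TNFRSF10B (-0.26) fell. CCNG1 (edgeR adjusted p = 0.0463) kept its call only without si NC replicate 1 (0.00552), with 0.102 to 0.133 without each of the others. In the 6 fits that left out a sample, XPC and TNFRSF10B kept the call in 1 each and GDF15 in 2. GDF15 and XPC lost the call after the GC correction (edgeR adjusted p = 0.804 and 0.079), where GDF15 stood at 0.02, and TNFRSF10B lost it after the GC and length correction (0.0767). After the GC correction the median was 0.36 (camera adjusted p = 0.000125), and the call was lost when only genes with a mean FPKM of at least 5 were kept (0.339). Of 16 nuclear noncoding RNAs and snoRNA host genes, 8 rose and 0 fell (10 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 0.00249, adjusted p = 0.128 with an estimated correlation). TUG1 rose by 0.57 and SNHG5 and SNHG6 by 0.59 and 0.64, and SNHG6 lost its call after the GC and length correction (log2 0.17, edgeR adjusted p = 0.159). Its GC-corrected median was 0.32 (camera adjusted p = 0.00805), and its call too was lost at a mean FPKM of at least 5 (0.0866).

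Respiratory chain genes were split by the genome that encodes them, a division not seen for the mitochondrial list under quantile normalization. Of 57 nuclear genes, 22 rose and 1, SDHA (-0.35), fell (27 and 1 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 6.1e-06, adjusted p = 0.445 with an estimated correlation). SDHA lost its call after the GC correction (edgeR adjusted p = 0.206) and kept it in 1 of the 6 fits that left out a sample. NDUFB3 of complex I rose from 34.1 ± 2.17 to 58.1 ± 8.70 FPKM and ATP5PB of ATP synthase by 0.57 on the log2 scale. Of 15 mitochondrially encoded genes, 9 fell and 1 rose (the same counts adjusted over the list alone), with a median of -0.41 (camera adjusted p = 0.0055, adjusted p = 0.455 with an estimated correlation). MT-CYB fell from 9572 ± 570.0 to 6280 ± 290.2 FPKM (n = 3 each, log2 -0.60) and MT-ND5 by 0.68, while the ribosomal RNA MT-RNR1 rose by 0.52. MT-CYB and MT-ND5 lost the call under quantile normalization (adjusted p = 0.13 and 0.0822) and MT-RNR1 after the GC and length correction (0.133). Mitochondrial genes took 19.3% ± 1.16 of all counts in si NC and 15.4% ± 0.997 in PLOD3 siRNA (SD, n = 3 each). Of 77 cytosolic ribosomal protein genes, 9 rose and 0 fell (1 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 1.3e-05, adjusted p = 0.526 with an estimated correlation), and RPL7 rose by 0.58 and RPS24 by 0.43. The share that rose was below that of all tested genes, 1945 of 12000. RPL7 lost its call after the GC and length correction (log2 0.17, edgeR adjusted p = 0.113), and RPL7 and RPS24 lost it under quantile normalization (0.0597 and 0.12). The GC-corrected medians of the 3 lists were 0.28, -0.58 and 0.29. Under quantile normalization the mitochondrial and the ribosomal protein lists lost their calls (camera adjusted p = 0.979 and 0.779, the latter with a median of 0.03). That method gives genes of equal rank the same value in every sample. A shared change of genes at the top ranks, where mitochondrial transcripts lie, is thus removed. The loss for the mitochondrial list therefore cannot decide whether it fell.

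**Figure D2:**
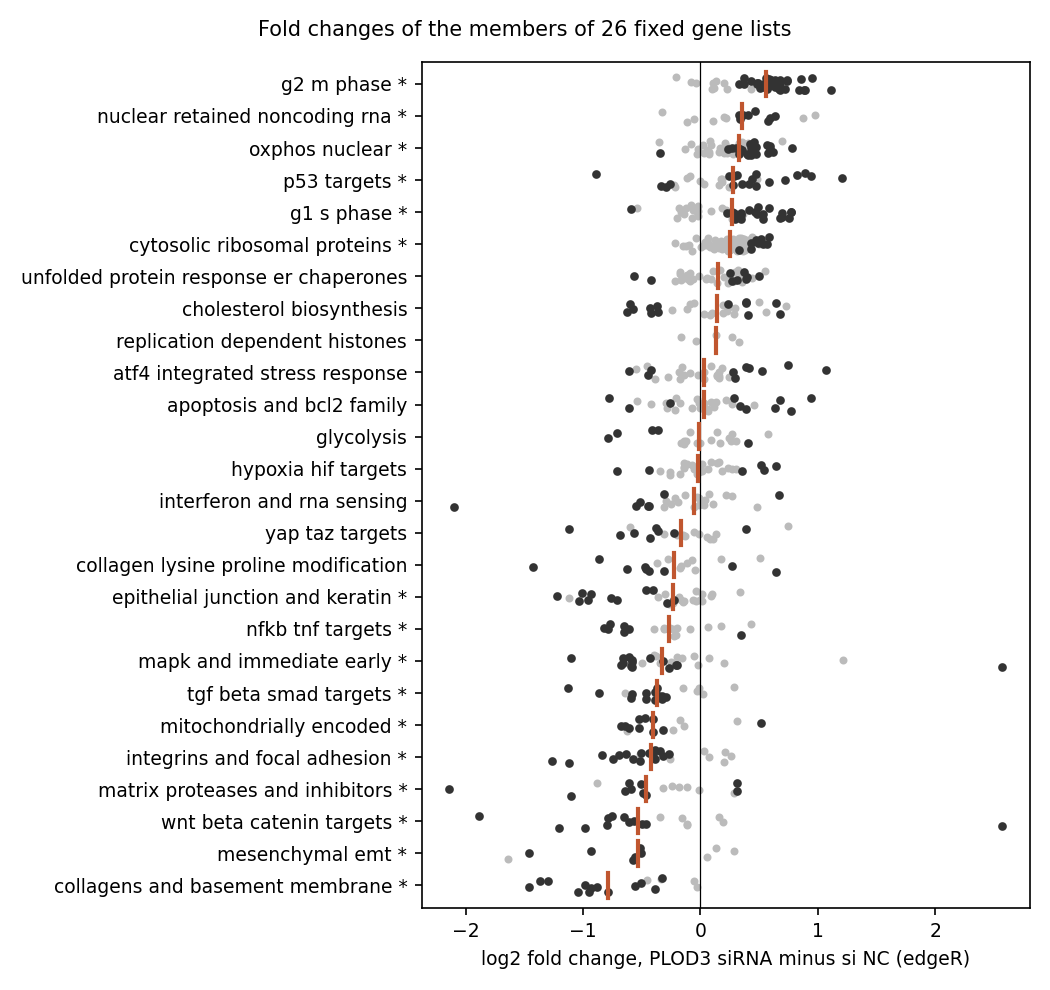
Log2 fold change (PLOD3 siRNA minus si NC, edgeR) of each tested member of the 26 lists. Dark points passed the gene test, grey points did not, the vertical bar is the list's median, and a star marks lists called by camera with the preset correlation. Medians run from -0.78 for collagens and basement membrane to 0.56 for G2 and M phase genes. Under quantile normalization, which gives genes of equal rank the same value, the mitochondrially encoded list's median is at 0.

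The other 9 of the 26 lists did not pass camera. YAP and TAZ targets had 7 of 21 members lower and NT5E higher (7 and 1 adjusted over the list alone, median -0.17, adjusted p = 0.087). Genes of the unfolded protein response had 7 of 36 higher, and EDEM2 and SYVN1 lower (4 and 0 adjusted over the list alone, median 0.15, adjusted p = 0.0926). Interferon genes had 6 of 25 lower and IFIT5 higher (3 and 1 adjusted over the list alone, median -0.05, adjusted p = 0.377), with BST2, a surface protein that tethers viruses, down by a log2 of -2.10. Genes of the ATF4 stress response had 7 of 31 higher, with DDIT3 at 1.07 and ATF3 at 0.75, and CEBPB, PHGDH and TRIB3 lower (7 and 3 adjusted over the list alone, median 0.03, adjusted p = 0.461). CEBPB, PHGDH and TRIB3 lost their calls after the GC correction (edgeR adjusted p = 0.269, 0.178 and 0.613). Cholesterol synthesis genes had 6 of 30 higher, among them ACAT2 at 0.64, and 7 lower, among them FASN at -0.63, whose edgeR call was lost after the GC correction at 0.0755 (7 and 8 adjusted over the list alone, median 0.14, adjusted p = 0.523). Hypoxia targets had KDM3A, P4HA1, BNIP3 and FAM162A higher and SLC2A1 and PLOD1 lower of 30 (3 and 2 adjusted over the list alone, adjusted p = 0.679), with a median of -0.02 but a mean of 0.02 and a test direction upward. Apoptosis genes had 7 of 31 higher, among them FAS at 0.94, and BCL2L1 (-0.78), BCL2L11 and TNFRSF10B lower (7 and 3 adjusted over the list alone, median 0.03, adjusted p = 0.679). Glycolysis genes had HK1 (-0.78), SLC2A1 (-0.71), PFKL and PKM lower and LDHB higher of 20 (4 and 1 adjusted over the list alone, median -0.02, adjusted p = 0.754), and PFKL, at -0.36, turned to 0.01 after the GC correction. LDHB lost its call after the GC and length correction (0.0546) and under quantile normalization (0.115). None of 5 histone genes was called by edgeR over all genes or adjusted over the list alone (median 0.13, adjusted p = 0.679), and 4 tested members were too few for intestinal differentiation, of which KRT20 fell (1 adjusted over the list alone).

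Of the 31 genes named because few members of their list moved that way, 8 kept the edgeR call on leaving out each sample, 14, 17 and 22 lost it without si NC replicate 1, 2 and 3, and 18, 15 and 9 without PLOD3 siRNA replicate 1, 2 and 3. Of the 31, 16 lost the call after the GC correction. With an estimated correlation 0 of the 26 lists were called by camera (lowest adjusted p = 0.128), and fry called 18, including 14 of the 16 that camera called. Those that fry did not call were the nuclear respiratory chain and ribosomal protein lists (fry adjusted p = 0.0557 and 0.123). Lists called by fry but not by camera were collagen modification, YAP and TAZ targets and interferon genes as lower (fry adjusted p = 0.00708, 0.0075 and 0.0217). The unfolded protein response list was called by fry alone as higher (0.0251).

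Annotation terms covered groups beyond the lists. Among the genes that rose were 28 of 41 proteasome genes (expected 6.86, adjusted p = 5.1e-11), 98 of 236 genes of mRNA splicing via the spliceosome (expected 39.5, adjusted p = 2.0e-16), 53 of 103 genes of ribosome biogenesis (adjusted p = 3.4e-13) and 40 of 87 of mitochondrial translational elongation (adjusted p = 2.2e-08). Among those that fell were 68 of 111 genes of the collagen-containing extracellular matrix (expected 23.7, adjusted p = 6.4e-17), 106 of 223 of cell adhesion (adjusted p = 1.1e-15), 59 of 113 of axon guidance (adjusted p = 1.4e-10) and 18 of 22 receptor tyrosine kinases (adjusted p = 3.7e-07). Among them too were 61 of 156 genes of Wnt signaling (adjusted p = 2.2e-05). The terms NIK/NF-kappaB signaling (30 of 56 rose, adjusted p = 3.6e-08), TNF-mediated signaling (33 of 81, 1.5e-05) and planar cell polarity Wnt signaling (29 of 76, 0.000244) passed mainly through proteasome genes. Of their genes that rose, 27 in each term are in the proteasome term, which leaves 3, 6 and 2 others. In all, 249 terms passed among the genes that rose and 326 among those that fell (one-sided Fisher's exact tests), and 173 and 198 of them also passed with the calls after the GC correction. When only calls past 1.5-fold entered, 218 terms passed.

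Fold changes went with the GC content of the transcripts. Across 11968 genes, which are not independent replicates, Spearman's rho of the log2 fold change with GC content was -0.499, and with transcript length, the other relation computed, -0.152. The median fold change was 0.30 in the tenth of genes with the lowest GC content (median 37.3%) and -0.36 in the tenth with the highest (64.4%). Within libraries, rho of the log2 level, relative to the mean of all 6, with GC content was 0.206, 0.59 and 0.335 in si NC and -0.45, -0.359 and -0.394 in PLOD3 siRNA. The median GC content was 60.3% in the collagen list, 56.6% in the integrin list and 43.2% in the G2 and M list. After the GC correction 1562 genes were higher and 1709 lower, 2445 of these calls were shared with the uncorrected test, and 14 of the 16 lists stayed called.

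**Figure D3:**
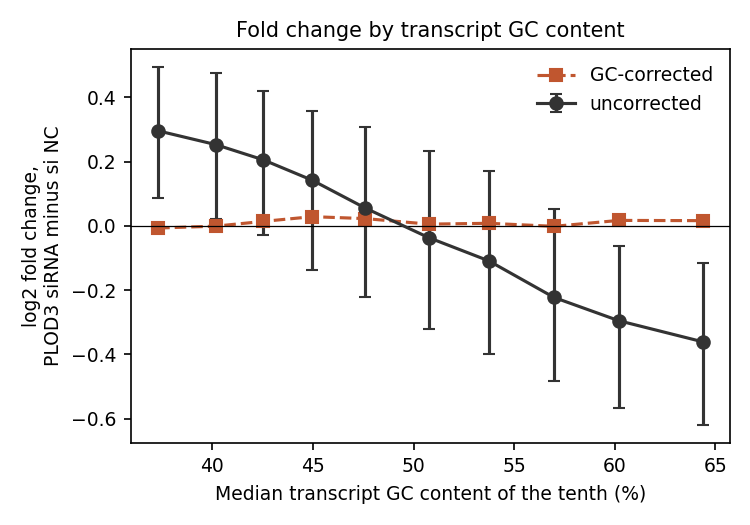
Median log2 fold change (PLOD3 siRNA minus si NC) against the median transcript GC content for 10 equal groups of the 11968 genes, with bars from the lower to the upper quartile. The uncorrected medians (circles) go from 0.30 at 37.3% GC to -0.36 at 64.4%, and the GC-corrected medians (squares) lie between -0.01 and 0.03.

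Markers of other cell types were low in both groups. Of 12 fibroblast markers 10, of 12 leukocyte markers 11 and of 10 endothelial markers 8 had an FPKM under 1 in every sample. The tested exceptions were COL1A1, at 2.35 ± 0.116 FPKM in si NC and 1.65 ± 0.239 in PLOD3 siRNA, FBLN1 at 3.26 ± 0.228 and 1.80 ± 0.139, CD68 at 0.807 ± 0.3997 and 1.55 ± 0.0361, ESAM at 2.55 ± 0.189 and 2.56 ± 0.262, and EGFL7 at 15.3 ± 1.67 and 9.58 ± 0.621 (SD, n = 3 each). Over all genes COL1A1, FBLN1 and EGFL7 fell and CD68 and ESAM did not pass, and adjusted over the list alone CD68 passed as well. The calls of COL1A1 and EGFL7 were lost after the GC correction (edgeR adjusted p = 0.26 and 0.0648).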

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

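The limma fit on log2(FPKM + 1) was the main test of the fixed design and became an alternative once the table was seen to hold counts. The edgeR fits with relative log expression scaling or with counts divided by 4, DESeq2 and both GC corrections were chosen after seeing the data. So were the fits without noncoding or step genes, and the other alternatives were fixed before. PLOD3 kept its direction and its call under every alternative, at a log2 of -0.92 to -0.77 on leaving out each sample (largest adjusted p = 0.0186) and -0.90 to -0.52 under the others (adjusted p = 2.7e-09 to 0.0208). Against 1767 in edgeR, 997 genes passed 1.5-fold in limma on log2(FPKM + 1) and 1692 with a pseudocount of 0.1, so most of that drop comes from the pseudocount of 1. With that pseudocount of 1, limma gave 995 without its trend, 1157 with sample weights, 994 when centred on each sample's median and 914 after quantile normalization, none of which was run with 0.1. In edgeR 1062 passed after the GC correction and 894 after the GC and length correction, and the cause was not tested. With a mean FPKM of at least 5, 6095 genes were tested rather than 12000, and 1192 were higher, 1354 lower and 820 past 1.5-fold, since fewer genes were tested. On log2(TPM + 1), 1461 were lower. TPM divides by a sample's summed FPKM, on average 396437 in si NC and 368551 in PLOD3 siRNA, which shifts fold changes upward. The median log2 fold change over all genes was 0.095, and how much of the drop this explains was not tested. Leaving out each sample, which leaves fewer samples, gave 1083 to 1651 higher, 1509 to 2011 lower, 1432 to 1916 past 1.5-fold, 384 to 516 terms and 16 to 18 lists. With calls past 1.5-fold, 218 terms rather than 575 passed, since fewer genes entered. Camera with an estimated correlation called 0 lists, against 16 with the preset one (fry called 18), and the cause was not tested. Among the called lists the estimate ran from -0.02 (p53 targets) to 0.58 (ribosomal proteins), against the preset 0.01. With the preset one, camera also called 12 lists in a split that mixed the groups and had 0 genes called. That split kept part of the group difference, so those calls need not be false. How far a preset call alone ties a list to PLOD3 siRNA is left open. PFKL, lower in edgeR, was at 0.01 (0.0118) after the GC correction and at 0.05 (0.0499) after the GC and length correction, and the cause was not tested. A replicate block gave 1471 higher and 1834 lower, with 3142 of the 4264 calls shared, but samples with the same number did not resemble each other more than others did. Of 131 called named genes, 98 kept the call under every alternative in which they were tested. Of the 16 called lists, 9 kept it under every alternative fit by camera with the preset correlation, and 0 with an estimated one. Each unit of count is less than 1 read pair, so depth limits what can be said of genes near an FPKM of 1.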

Other observations

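Of the tests here, that of the GC trend within the ribosomal protein list and those of the step genes by library and by group were written before their results were seen, and all others after. Genes of chaperones and their partners, most of them cytosolic and HSPD1 and HSPE1 mitochondrial, a list written because HSPA8 stood out, were higher in PLOD3 siRNA: 23 of 31 rose and 0 fell, with a median log2 fold change of 0.43 (camera adjusted p = 1.116e-10, adjusted p = 0.0623 with an estimated correlation). HSPA8, a constitutive chaperone of the HSP70 family, rose from 280 ± 7.91 to 588 ± 53.4 FPKM, HSP90AA1 from 345 ± 21.1 to 643 ± 14.3, and CCT8, of the chaperonin that folds actin and tubulin, from 90.0 ± 5.72 to 146 ± 12.9 (n = 3 each). Before correction the members not called were HSPE1 (log2 0.43), DNAJB6 (0.23), DNAJB1 (0.09), HSPA1B (0.04), HSPA1A (-0.06), PTGES3 (-0.12), BAG3 (-0.13) and HSPB1 (-0.26). After the GC correction 19 rose and 0 fell (camera adjusted p = 1.2e-10). The list stayed called without HSPA8 (1.249e-09 uncorrected, 9.27e-10 corrected), so HSPA8 may be part of a shared rise of many, but not all, of these genes.

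Notch pathway genes, a list written because NOTCH3 stood out, were lower: 12 of 16 fell and 0 rose, with a median of -0.54 (camera adjusted p = 7.229e-07, adjusted p = 0.0623 with an estimated correlation). The receptor NOTCH3 fell from 5.41 ± 0.373 to 1.78 ± 0.0401 FPKM, the ligand JAG1 from 5.70 ± 0.322 to 2.57 ± 0.176 and the target HES1 from 6.64 ± 0.842 to 4.45 ± 0.0594 (n = 3 each). After the GC correction the median shrank to -0.35 and 6 fell (adjusted p = 0.000226, or 0.0019 without NOTCH3). Of the targets HES1, HES2, HES4, HEYL and NRARP only HES1 still passed, HES4 and NRARP stood at 0.08 and 0.10, and NOTCH1, NOTCH2, JAG2 and RFNG did not pass. NOTCH3 may thus be part of a fall of some Notch genes, such as JAG1 and DLL1, while a fall of Notch signaling as a whole is left open. HMOX1 is a target of the oxidative stress factor NRF2, but the list of NRF2 targets went both ways, with 11 of 27 higher and 6 lower (median 0.04, camera adjusted p = 0.54). TXNRD1 rose by 0.97, while the transporters ABCC2 and ABCC3 fell (log2 -1.09 and -1.11), which leaves open whether NRF2 acted.

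Fold changes fell with rising GC content. Within the ribosomal protein genes, which share one function, rho with GC content was -0.3364 (SE 0.115), a candidate explanation being recovery that depends on GC content and differs between libraries. Of the 3 other lists looked at, rho was -0.536 (SE 0.134) for nuclear respiratory chain genes, -0.722 (SE 0.16) for G2 and M genes and -0.24 (SE 0.25), within its error, for collagens. After removal of the GC trend, 14 of the 16 lists stayed called in the same direction by camera with the preset correlation. This cannot exclude the trend as the whole cause of the list calls, as they rest on the preset correlation. That setting also called up to 12 lists in splits mixing the groups, although these kept part of the group difference. With an estimated correlation the lowest camera adjusted p after the correction was 0.134. In the G2 and M list 27 genes still rose by the gene test, and in the collagen list 10 still fell. A response of the cells that happens to follow GC content cannot be told apart from GC-dependent recovery, as the trend parts the groups: a two-sided exact permutation test of the library slopes gave p = 0.1, the smallest that 3 against 3 libraries allow.

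In 148 of 6095 genes with a mean FPKM of at least 5, MYC among them, levels differed at least 3-fold between replicates of one group, in 186 steps. One faulty library is argued against, since the most frequent odd library took 20.97% of the steps, and so are more variable levels under PLOD3 siRNA, as that group held 52.69%. Reads moved between overlapping gene models stay open: of the 74 genes that could be tested, 60.81% (SE 5.67) lost the step when overlapping genes on the same strand were summed, but so did a median of 54.1%, and at most 58.1%, in 200 draws that added unrelated genes of like level, a gap within 2 SE. For 69 genes, MYC among them with a ratio of 12.4, no such model exists and the test says nothing, and no biological explanation was tested.

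The signal recognition particle, 7SK, RNase P and RNase MRP RNAs had a median log2 fold change of 4.424 and the 5.8S rRNA copies one of 3.523. The former, which are not rRNA, argue against less complete removal of rRNA alone, and the latter, copied by RNA polymerase I, against more output of RNA polymerase III alone. Equally better recovery of all RNA without a poly(A) tail stays open. The 44 small nucleolar RNAs had a lower median of 0.806 (SD 0.755). Their highest value was 2.93, against 3.5 for the lowest 5.8S copy. However, models of small nucleolar RNAs can overlap other genes on the same strand. SNORD30, with 1 such overlap, stood at 0.127, 8.31 and 11.5 FPKM in si NC replicates 1 to 3. Reads of other genes may thus count in them, and their median cannot decide the question. The 16 histone genes, most of whose messages lack a tail, had a median of 0.4612 (SD 0.856). Messages with and without a tail were not told apart there, so that median cannot decide the question. H2AC17, H1-4, H2AC14 and H2AC13 rose most, by 1.75 to 2.27, with 1 of the 16 called. A recovery that depends on other features, such as length or structure, was not tested. A response of the cells to PLOD3 siRNA was not tested for these RNAs.

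The 6 samples make 10 splits of 3 against 3, too few for a share under 0.05, and for each result 1 of the 10, the real split, gave a value as large. The real split gave 1945 genes higher, 2319 lower and 1767 past 1.5-fold, and the highest of the others 2, 3 and 5. Of the lists 16 were called, against 12 in the highest other split, and of the terms 575 passed, against 0.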
